A study of Metarhizium robertsii with 2 samples.

How the data were processed

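RNA recovered by co-immunoprecipitation with Argonaute from Metarhizium robertsii was analysed from 2 tables, 1 for small RNA and 1 for mRNA. Neither table was tied to a sample by its source, so each was assigned through the name of its worksheet: the small RNA sheet to the only small RNA sample, and the mRNA sheet to the remaining sample. Each group held 1 sample. Per the file headers, the small RNA table gave the length, an expected count and the bases of each distinct sequence; every deposited count was a whole number and was used as a read count, without rounding. A total of 22 lines of this table had been emptied and were not analysed here. Per the file headers, the mRNA table gave gene, transcript, length and FPKM as computed by the authors, that is, fragments scaled by gene length and library total. The aligner, the counting tool, the genome build and the trimming of adapters are not given in the sources used here. All coding lengths were multiples of 3, so the gene models held no untranslated regions.

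Which results would be described, the 1-library design without tests between groups, and a first set of alternatives were fixed before the data were examined. The rule for named items, fixed then too, took the 10 small RNAs with most reads, the most abundant of each length from 18 to 30 nt, up to 10 named in the table as miRNAs (the table named none), the 20 genes with the highest value, members of 16 lists of gene products, and any RNA interference component. Genes and sequences outside it were chosen after their values were seen: the 2 rRNA fragments whose bases are given, the individual miRNAs, the genes highest by reads and the 3 pairs of genes without whole reads. Sequences of bacterial or animal type and those of unknown origin are not printed.

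No genome was used here and the reference table paired locus tags with no product names (assembly MAA 2.0, used for gene identity, locus tag order and annotated span; 877 of the 886 listed genes matched among 11688). The planned matching of small RNAs to the genome, their strand relative to genes, the 16 gene lists, the seed matches in mRNAs and the small RNA density on genes were therefore not run. Origin was instead read from 7 rRNA strings (fungal 18S and 5.8S, animal 5.8S and 5S, bacterial 16S, 5S and part of 23S) and 62 miRNAs, 47 animal and 15 plant. These were typed from general knowledge, not from a file, after the most abundant sequences had been looked at; 3 of the animal miRNAs had been recognised among them. A small RNA was assigned to rRNA when it lay wholly within a string, and to a miRNA when its first 18 nt were identical. Strings written backwards and reverse complements served as controls. Only sequences up to 37 nt entered base results or were matched, because 98.1% of those of 38 nt and over held bases of a sequencing adapter, against 0.933% of shorter ones. Shares of reads by class were taken over all reads, so the 13179 reads of 38 nt and over counted as unmatched there.

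Read counts without molecular identifiers are not independent molecules. For sequences with over 10 reads, the number of molecules was estimated as the count divided by the median count, within 15 to 90 reads, of sequences of the same length, rounded and at least 1, which takes the peak for 1 molecule, an assumption weighed in the closing section; lengths with fewer than 200 sequences in that window, from 30 nt up, were left out. Shares have exact binomial (Clopper-Pearson) 95% intervals and gene reads exact Poisson 95% intervals; a count of 0 was taken to allow 3 counts. All of them cover counting error only. Reads per gene were recovered from FPKM by finding the length offset and the value of 1 read that made most genes whole (offset 36 nt; 719 FPKM per read for 1 kb). The molecule estimate, the read recovery, the inner-position base shares and the looser rRNA match with up to 2 mismatches were chosen after seeing the data. FPKM is already divided by length, so the planned length correction was replaced by recovered reads.

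Both estimates were tested on simulated data. With 886 simulated genes, 100% of read numbers were recovered at each of 2 offsets. With 20000 simulated sequences, 90.8% and 91.2% of molecule numbers were recovered at 2 amplification levels, with totals 1.01 and 1.04 times those set; this simulation assumed that 1 molecule gives the peak count, so it checks the arithmetic and not that assumption. Annotated spans and consecutive locus tags were compared with 10000 random gene lists, and ratios of medians have intervals from 2000 bootstrap resamples (500 for commonest counts, read from the peak of a smoothed histogram of log-scaled counts). Alternatives counted distinct sequences or molecules, left out the 10 most abundant sequences, required at least 10 reads, left out rRNA matches, or restricted the length. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.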

Results

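RNA co-immunoprecipitated with Argonaute, the protein that carries small RNAs to their target transcripts, was sequenced from the insect-pathogenic fungus Metarhizium robertsii. The labels describe wild-type fungus grown from conidia in SDAY, a rich sugar and peptone medium, at 25 °C for 2.5 days. The method named for the series was HITS-CLIP, in which RNA attached to a protein is recovered with an antibody and sequenced. There were 2 samples in 2 groups, 1 of small RNA and 1 of longer RNA, and no control sample was analysed here. The small RNA table listed 124456 distinct sequences of 18 to 44 nt with 5935262 reads in all. The mRNA table listed 886 genes as FPKM. With 1 sample per group no difference between groups could be tested, and no value had a replicate check. The labels named strain ARSEF 23 and antibody MrAGO1 for the longer RNA, but ARSEF 24 and MrAGO2 for the small RNA, while the design text spoke of a single Argonaute protein, so which protein each library came from is uncertain.

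The first question was which small RNAs the Argonaute preparation held, beginning with their size. The small RNAs formed a broad distribution centred on 21 and 22 nt. The 21 nt class held 14.3% of reads and the 22 nt class 14.1%, against 13.001% at 20 nt, 11.3% at 23 nt and 11.2% at 24 nt. By reads the short end did not fall away, since 18 nt sequences held 11.6% and 19 nt sequences 11.5%. It was lower on the other counts. Of distinct sequences, 8.89% were of 18 nt and 9.32% of 19 nt, against 11.9% at 22 nt. Of estimated molecules, the shares were 9.88% and 9.99%, against 13.2% at 22 nt. Beyond 24 nt the shares of reads fell steadily, to 6.25% at 25 nt, 3.71% at 26 nt and 0.751% at 28 nt. Sequences of 20 to 24 nt held 63.8% of reads but 56.0% of distinct sequences. The share at these lengths differed between RNA classes: 97.6% of reads matching animal miRNAs lay at 20 to 24 nt, against 73.1% for bacterial rRNA, 60.9% for eukaryotic rRNA and 61.8% for reads that matched no marker. The bacterial value rested on a few abundant fragments: with each repeated sequence counted once it was 52.9%, against 55.1% for eukaryotic rRNA, 56.1% for unmatched sequences and 86.9% for animal miRNAs.

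**Figure D1:**
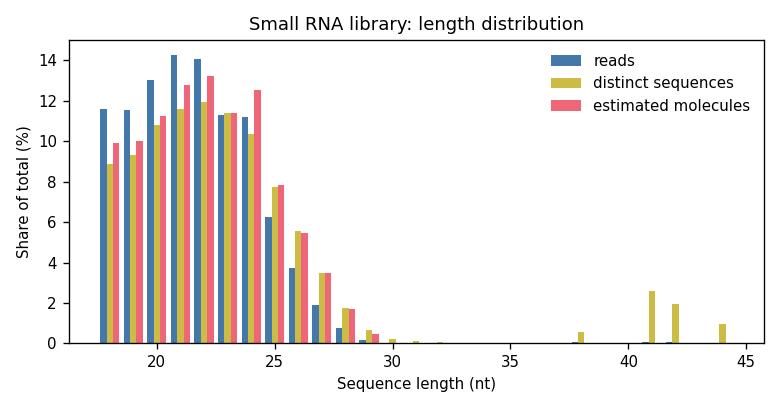
Share of reads, of distinct sequences and of estimated molecules (vertical axis, percent) at each sequence length (horizontal axis, nt) in the small RNA library. Reads were most frequent at 21 nt (14.3%) and 22 nt (14.1%), and the separate group of distinct sequences at 38 nt and over held 0.222% of reads.

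The next question was whether the small RNAs shared a 5′ base, since many Argonaute proteins favour small RNAs that start with uridine. Uridine was about as frequent at the 5′ end as inside in the library as a whole. It began 19.4% of estimated molecules (exact binomial 95% interval 19.2 to 19.6%) and filled 20.02% of the inner positions of the same molecules; counted once per repeated sequence the order turned, with 21.4% at the 5′ end and 20.99% inside. Cytidine and adenosine were more frequent at the 5′ end than inside, with 31.5% against 25.2% for C and 26.6% against 23.4% for A, whereas guanosine was less frequent, with 22.5% against 31.3%. At the 3′ end cytidine reached 35.8% and uridine 28.9%, and guanosine was at 16.97%. The interval covers counting error only, and the 5′ cytidine excess was smaller, 26.6% against 24.2%, when each of 43263 repeated sequences was counted once.

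Uridine at the 5′ end varied with length and class. It began 26.02% of reads at 22 nt, 22.1% at 21 nt and 21.7% at 23 nt, but 16.9% at 18 nt and 15.3% at 24 nt. Cytidine began 39.04% of 24 nt reads, but 28.9% without the most abundant 24 nt sequence, when adenosine began 29.5%. Counted once per repeated sequence, uridine began 20.99% at 18 nt, 24.2% at 22 nt and 20.8% at 24 nt. Fragments of eukaryotic rRNA started with U in 29.8% of estimated molecules (28.4 to 31.3%), above their inner share of 22.8%. Fragments of bacterial rRNA did so in 10.4% (9.91 to 11.01%), below their inner share of 18.6%, and unmatched small RNAs in 18.2% (17.9 to 18.4%) against 19.98% inside. Single fragments set the class values: without the commonest 18S fragment family 19.8% of eukaryotic rRNA reads began with U, and without the commonest 23S family 15.6% of bacterial rRNA reads did. Counted once per repeated sequence, the shares were 24.1% (21.5 to 26.7%) for eukaryotic rRNA, with 23.2% inside, 18.6% (16.5 to 20.8%) for bacterial rRNA, with 21.1% inside, and 21.2% (20.8 to 21.6%) for unmatched sequences, with 20.9% inside. On that count the eukaryotic excess lay within the interval, and the deficit of unmatched sequences was not seen.

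**Figure D2:**
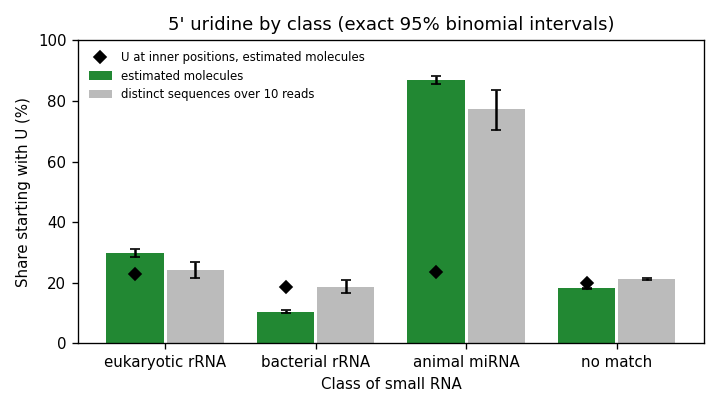
Share of small RNAs that start with U (vertical axis, percent) in 4 classes, as estimated molecules and as distinct sequences with over 10 reads; error bars are exact binomial 95% intervals and diamonds give U at inner positions. As molecules, eukaryotic rRNA (29.8%) lay above and bacterial rRNA (10.4%) below its diamond; the animal miRNA bars (87.0% of molecules) are fixed by the matched sequences, since matching started at their first base.

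The third question was where the small RNAs came from. Known ribosomal RNAs took 15.005% of reads by exact sense match to 7 rRNA strings, and a further 135 reads in 2 sequences matched the opposite strand. Fungal-type 18S rRNA, the RNA of the small ribosomal subunit, gave 202256 reads in 1018 sequences that covered 78.3% of its string. Fungal-type 5.8S rRNA, part of the large subunit, gave 18000 reads in 162 sequences. Of the bacterial strings, the segment of 23S rRNA, the large subunit RNA, had 500669 reads, 16S rRNA of the small subunit 159196, below fungal-type 18S, and 5S rRNA 3072. The animal 5S string had 6165 reads and the animal 5.8S string 1213. No fungal 25S or 28S string was used to set against 23S. No read matched the strings written backwards, which allows a share of up to 5.05e-05% of reads per string. With up to 2 mismatches the rRNA share rose to 29.9%, of which bacterial strings took 20.01% of all reads and eukaryotic strings 9.70%. The strings were typed from general knowledge and no fungal genome was used here, so the 82.5% of reads with no marker were not placed. Class shares may be too low for that reason. They may also be too high where a stretch is shared with an rRNA that had no string.

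The most abundant exact 18S fragment was TTGACTCGTTCGGCACCTTACG, 22 nt long, at bases 1059 to 1080 of the string, with 15258 reads (268 estimated molecules). The most abundant exact 5.8S fragment, ATCATCGAATCTTTGAACGCACA, was 23 nt long, lay at bases 88 to 110 of its string and had 947 reads (18 estimated molecules). Both were chosen after their values were seen. Neither fragment was assigned to Metarhizium itself, because related fungi share these sequences.

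Animal microRNAs made up a further 2.49% of reads, with 147919 reads whose first 18 nt equalled an animal miRNA. miR-486, abundant in vertebrate blood cells, took 63255 of them (42.8%). It was followed by miR-143, known from smooth muscle, with 10243 reads, miR-10b with 8892, miR-181a with 8592, miR-10a with 7928 and miR-92a with 6062. miR-21 had 5774 reads, miR-26a 5384 and let-7f 5117. Of 47 animal miRNAs examined, 19 had over 1000 reads and 5 had 0, among them miR-122 and miR-223. Of 15 plant miRNAs taken as controls, 4 had 10 or more reads, led by miR166 with 6233, and reversed animal miRNAs had 0.

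Bacterial ribosomal fragments were frequent among the most abundant small RNAs, of which the first 10 together held 7.02% of reads. Of the 10 most abundant sequences, 6 matched bacterial rRNA and 1 eukaryotic rRNA within 2 mismatches, 1 was miR-486 and the remainder had no match. Of the 10, 9 began with C, but several of these were versions of the same fragment and so not separate cases. A 24 nt sequence ranked highest, with 94867 reads (1.598%), and matched bacterial rRNA only with mismatches. A 21 nt exact match to the bacterial 23S segment had 90448 reads (1.52%), and versions of the same piece at 20, 22 and 24 nt had 40025, 34477 and 31912. The 22 nt form of miR-486 had 30171 reads, a 20 nt relative of eukaryotic rRNA 24394, and a 25 nt sequence with no match 24146. An 18 nt sequence with no match had 23492 reads and an 18 nt relative of bacterial rRNA 22512. Starts were sharply defined for 2 of these: among reads sharing its central 12 nt, miR-486 kept the same start in 99.5% but the same end in only 50.1%, and the unmatched 18 nt sequence kept the same start in 99.8% and the same end in 97.3%. The shortest sequences listed were of 18 nt, so forms of the unmatched 18 nt sequence trimmed at either end could not be seen. The 20 nt eukaryotic rRNA relative kept its start in only 37.2%.

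The most abundant sequence of each length from 18 to 30 nt was a bacterial rRNA match, exact or within 2 mismatches, at 8 of the 13 lengths. The 5 exceptions, with no match, were the 18 and 25 nt sequences named already and those at 26 nt (5517 reads), 29 nt (455) and 30 nt (186). Among the bacterial matches, the 19 nt sequence had 21262 reads, the 23 nt one 21938, the 27 nt one 5041 and the 28 nt one 1381. Several were versions of the same fragment. Those at 20, 21 and 28 nt shared their central 12 nt (355645 reads), as did those at 19 and 22 nt (355286 reads) and at 23 and 24 nt (335833 reads). The 27 nt one shared its own with the 18 nt relative of bacterial rRNA (320543 reads). The 8 lengths are therefore not separate cases. The table gave sequences without names, so no fungal miRNA-like RNA was named from it.

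Read counts per small RNA sequence piled up around a single value: 34095 sequences, 78.5% of those with over 10 reads, had 15 to 90 reads, with a median of 53. The bin from 51 to 55 reads held 4040 sequences and the bin from 11 to 15 held 751. The median fell with length, from 63 reads at 18 nt to 57 at 22 nt, 48 at 24 nt and 24 at 28 nt. Dividing each count by the median for its length gave 109729 estimated molecules at 53.1 reads each, an estimate that takes the peak for 1 molecule. It is the unit behind the class and base intervals given for estimated molecules, while those counted once per repeated sequence do not use it. A further 70217 sequences had 1 read each and together held 1.18% of reads.

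**Figure D3:**
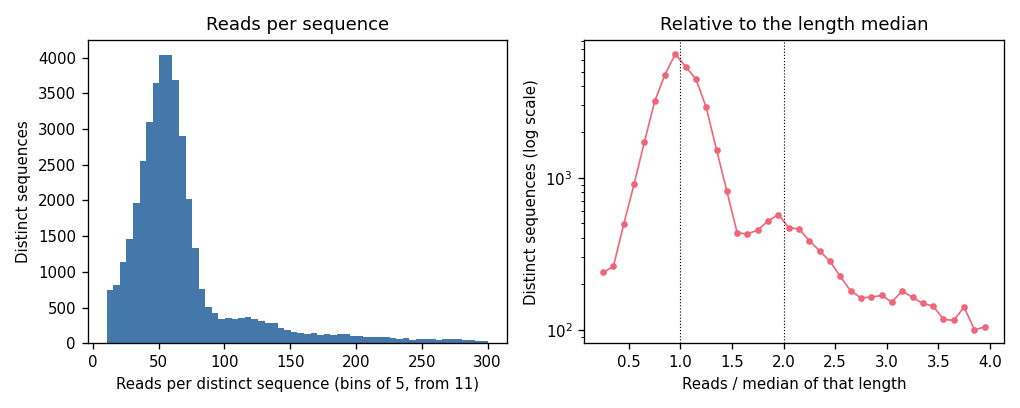
Left, number of distinct sequences (vertical axis) by reads per sequence in bins of 5 from 11 reads (horizontal axis); right, the same sequences by reads divided by the median of their length (horizontal axis), on a logarithmic vertical axis with dotted lines at 1 and 2. The commonest bin, 51 to 55 reads, held 4040 sequences, and on the relative scale counts rose again from 427 at 1.6 to 1.7 to 573 at 1.9 to 2.0.

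The last question was which transcripts the Argonaute preparation held. One gene stood far above the rest: MAA_07556, with a coding length of 999 nt, had an FPKM of 94783, which was 14.2% of the summed FPKM. MAA_04116 followed with 6188 (849 nt), MAA_02094 with 5773 (534 nt), MAA_09868 with 5097 (318 nt) and MAA_08906 with 4520 (513 nt). The next 15 genes by FPKM ran from MAA_02681 at 3576 through MAA_06929, MAA_06687, MAA_01404, MAA_07037, MAA_04335, MAA_00378, MAA_09216, MAA_07279, MAA_09262, MAA_03623, MAA_02351, MAA_08240 and MAA_03730 to MAA_09211 at 2246. The median over the 886 genes was 468 and the lowest value 25.5. Genes are given by locus tag because gene products were not used here, and so no pathway or gene family could be described.

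Read numbers behind these values were small. In 880 of the 886 genes (99.3%) the FPKM was a whole multiple, within 0.05 reads, of the value of 1 read over the coding length less 36 nt. That value implied a total of 1391 reads in the FPKM scaling, with 1358 in listed genes. Whether further reads were sequenced but left out of that total is not known here. MAA_07556 had 127 of the reads in listed genes (exact Poisson 95% interval 106 to 151), or 9.35% (exact binomial 7.86 to 11.03%). These intervals and those that follow treat each read as an independent molecule. Copies of the same molecule could not be told apart here. MAA_00378 had 9 (4.12 to 17.1), MAA_04116 and MAA_07632 had 7 each (2.81 to 14.4), MAA_00868 had 6 and MAA_06371 and MAA_04771 had 5 each. The other genes had fewer: after rounding, 641 (72.3%) had a single read and 178 had 2, each count including 3 genes whose reads were not whole. By reads, the order of the 6 other genes with 5 or more reads was not resolved, since their intervals overlapped.

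With 1 or 2 reads in most genes, the division by length in FPKM set much of the order by FPKM. Across genes, which are not independent replicates, Spearman's rho between coding length and FPKM was −0.832, a value largely fixed by that division, and between coding length and reads 0.133. Of the 20 genes highest by FPKM, 6 were among the 20 highest by reads and 9 had 1 or 2 reads. Ties in reads, as among the 15 genes with 4, were ordered by FPKM, which favours such overlap. The median coding length of the 20 genes highest by FPKM was 624 nt against 1809 nt for all listed genes. MAA_00868, among the genes with most reads, had an FPKM of 354 over a listed coding length of 12225 nt, although the reference annotation gives it a span of 5258 nt. Coding length exceeded the annotated span in 70 of 877 genes (7.98%), MAA_00378 and MAA_09216 included, so the gene models of the table and of the reference differ. The 6 genes without a whole number of reads formed 3 pairs whose reads summed to whole numbers within 0.002: MAA_00095 with MAA_00417 (4), MAA_00382 with MAA_10516 (3) and MAA_10348 with MAA_00502 (2), and their levels are uncertain.

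**Figure D4:**
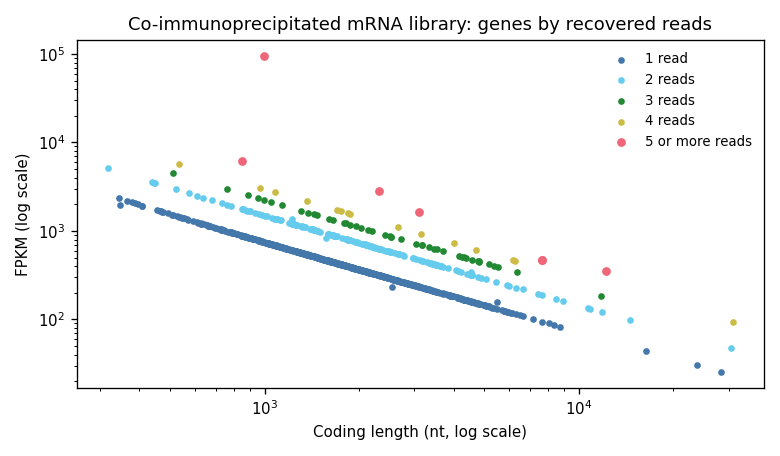
FPKM (vertical axis, log scale) against coding length in nt (horizontal axis, log scale) for the 886 listed genes, 1 point per gene, coloured by recovered reads. Genes with 1, 2 or 3 reads lie on separate falling lines, and MAA_07556 with 127 reads stands apart at an FPKM of 94783.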

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

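The tests of an animal source, of bacterial RNA and of the fungal mitochondrion were chosen after the results were seen, and the test with reversed sequences was chosen before its result was seen.

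Animal miRNAs stood out because a fungal library held 147919 reads that began with one, against 0 for the same sequences written backwards. Chance matching of short sequences is argued against by that control, in which 0 of 44 reversed miRNAs reached 10 reads. RNA of an animal source may account for the pattern: 37 of the 44 animal miRNAs not looked at beforehand had 10 or more reads. The test at first also required that under 1 in 10 plant controls match. That clause was dropped after 4 of 15 did (6805 reads over all 15). Plant RNA, or exchange of reads with other libraries, therefore stays open beside an animal source in the culture or reagents. No biological explanation was tested, since there was 1 library and no control.

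Bacterial rRNA stood out with 662937 reads, 11.2% of the library, against 0 for the strings written backwards. The fungal mitochondrion, whose ribosome lacks a 5S rRNA, is argued against as the only source by 3072 reads of bacterial 5S. Bacterial RNA in the sample is a candidate explanation: 159196 reads matched bacterial 16S and no eukaryotic string, spread over 79.8% of its length. No mitochondrial rRNA was among the eukaryotic strings, so this match cannot separate bacterial 16S from a mitochondrial RNA that shares its stretches. The family around the commonest 23S fragment alone held 5.999% of reads. Whether such RNA came from the culture, the antibody preparation, the enzymes or another library was not tested, and no biological explanation was tested.

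Sequences of 38 nt and over lay outside the main measurement, with 13179 reads in 7569 sequences, and 98.1% of those sequences held adapter bases.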

How the results depend on the processing

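The estimates by molecules, by recovered reads and with up to 2 mismatches were chosen after the results were seen; the other alternatives were fixed before the data were examined. No paired analysis was possible because each group held 1 sample, and for the same reason no replicate could be left out. The share of reads at 20 to 24 nt, 63.8%, was 56.0% over distinct sequences, 62.3% without the 10 most abundant, 63.9% with at least 10 reads, 61.2% over estimated molecules and 62.7% without rRNA matches. The share starting with U, 19.5% of reads, was 20.9%, 20.4%, 19.4%, 19.4% and 20.3% under the same settings in that order, and 20.8% at 20 to 24 nt; at least 10 reads stayed within the interval of the reads, and the molecules' own interval, 19.2 to 19.6%, held the value of the reads. The rRNA share, 15.005% of reads, was 2.15% over distinct sequences, 12.6% without the 10 most abundant, 15.3% with at least 10 reads, 14.7% over molecules and 29.9% with up to 2 mismatches. MAA_07556 held 14.2% of summed FPKM, 17.8% among genes above the median value by construction, and 9.35% of recovered reads. MAA_04116 held 0.928% of summed FPKM with MAA_07556 included and 0.569% of recovered reads with MAA_07556 left out. These shares of MAA_04116 have unlike totals and cannot be compared directly. The causes of the other changes were not tested. Not run were the strand of small RNAs relative to genes, gene lists, seed matches, small RNA density on genes, genome-unique matches, removal of tRNA and division of FPKM by length. With 1391 mRNA reads implied by the FPKM scaling, the order by reads of the 6 genes after MAA_07556 was not resolved.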

Other observations

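The tests of a second rise in read counts (both), of the commonest count and of expression levels were chosen after the results were seen; those of the median shared by unrelated RNAs and of neighbouring genes were chosen before theirs.

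Genes of the mRNA table were longer than the genome's genes at large. The listed genes had a median annotated span of 1937 nt, against 1346.5 nt for all 11688 reference genes, and the highest median among 10000 random lists of the same size was 1494 nt. Without the 70 genes whose listed coding length exceeded that span, the median was 1982 nt. These random lists gave every gene the same weight, whereas a longer gene can draw more reads. The comparison therefore cannot tell whether longer genes were recovered preferentially. The median coding length was 1734 nt for genes with 1 read, 1953 nt with 2, 2529 nt with 3, 1866 nt with 4 and 3093 nt with 5 or more.

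Small rRNA fragments were spread along their parent RNAs but with sharp peaks. On the fungal 18S string the most covered base, 1074, carried 37362 of 202256 reads, and on the 5.8S string the most covered base carried 13398 of 18000. On the bacterial 23S segment base 35 carried 351133 of 500669 reads.

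Read counts per small RNA piled up near a single value that fell with sequence length. Amplification copies of single molecules stay open as an explanation, since no test run decided. The first comparison called for more sequences at 1.9 to 2.1 times the peak than in a lower range, and the ratio was 0.975 (0.894 to 1.06). That lower range took in the falling side of the main peak, with 817 sequences at 1.4 to 1.5 times and 434 at 1.5 to 1.6 times. Such a ratio could arise with or without a second rise, so the first comparison cannot decide. Against 1.6 to 1.8 times the peak the ratio was 1.18 (1.08 to 1.29), but that range was picked at the dip of the same histogram, so this only restates the pattern. Bacterial and eukaryotic rRNA fragments of 20 to 22 nt had commonest counts of 61.8 and 59.3 reads, a ratio of 1.04 whose interval (0.979 to 1.11) just passed the 10% margin set. Their medians within 15 to 90 reads, at a ratio of 1.03, are largely fixed by that range. The 13739 unmatched sequences of these lengths with over 10 reads had a commonest count of 60.9. The 91 sequences of animal miRNAs had one of 280.03 (115 to 535). Gene expression levels stay open as well, since they do not forbid the fall with length, to 0.597 of the 20 nt median at 26 nt, and no biological explanation was tested.

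Most sequences with few reads resembled abundant ones. Of 73516 sequences with 1 to 10 reads and under 38 nt, 78.9% differed by 1 substitution from a sequence with over 10 reads, against 14.1% of 26761 sequences with 41 to 100 reads. With insertions and deletions of 1 base counted too, the shares were 86.2% and 38.7%.

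The hypothesis that neighbouring genes were recovered together found no excess: 56 pairs of listed genes had consecutive locus tags, within the 52 to 81 of random lists weighted by gene span.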
